A study of Rattus norvegicus with 4 samples.

How the data were processed

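Gene expression was measured by RNA sequencing in eye and retina of wild-type Long Evans rats. The labels list 4 samples, 2 technical replicates for each of 2 tissues, and say that each library was pooled from RNA of 5 rats. Samples were grouped by the tissue in their titles. A single column of values was analysed per tissue, and whether it joins both technical replicates is not given in the sources used here. Per the submitters' processing notes, GSNAP and HTSeq were used, with the rat genome build rn4. Their versions, their settings, the gene annotation and the use of strand are not given in the sources used here.

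The unit of the deposited values is taken here as RPKM. It was inferred from the values themselves, since neither the labels nor the files name it. Counts of reads and of fragments cannot be told apart in this way, and they are called reads here. If a value is a number of reads divided by gene model length and by the library's total, a gene's values in both libraries are set by whole reads, a whole length and the same 2 totals. Among 1472 short genes, 69 gave the same eye total, and the next most common total came from 21. The totals came out at 28071917 reads for eye and 51944762 for retina, within 0.0003 and 0.0019 of a whole number, a ratio of 1.85. With them, 13978 of 13980 genes searched had whole reads in both libraries, within the rounding of the printed decimals. The reads found are the smallest that fit, and the true reads may be a shared multiple of them, so intervals made from them are if anything too wide. They sum to 71.4% of the eye total and 63.7% of the retina total. For 130 genes the smallest length equalled the gene span in the reference table.

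Each file held 14533 rows, of which 7 had ND in place of a value, and 41 gene names stood on more than 1 row, leaving 14485 names. For 401 of these names the values kept had at most 5 decimals. Of 17 names with both kinds of row, of which the finer was kept, 8 with finer values above 5 in both libraries were compared, and the median ratio of the coarse to the fine value was 1.01 in each library. The 401 were kept, without recovered reads, and left out in an alternative. Listed at 0 were 168 genes in eye, 265 in retina and 104 in both. Gene names were used as the files give them, and older symbols were matched through the synonyms of a reference table of the rat assembly GRCr8, whose build differs from rn4, so no coordinates are given.

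The tests had been fixed before the data were examined for counts as well as for normalized values. As the files held normalized values, taken as RPKM, the branch for normalized values was used. The fold was log2((eye + 0.1) / (retina + 0.1)), among the 13259 genes with a value of at least 1 in either library, and a gene was called at a fold of at least 2. Adding 0.1 understates the change of genes with low values. Folds and values of named genes are ratios and values as deposited, without the added 0.1. Exact 95% intervals of the fold come from the Clopper-Pearson interval of the recovered reads. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only, and they compare the 2 libraries, not the tissues.

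The 22 gene lists, written before the data were examined, covered rod photoreceptor, cone photoreceptor, shared photoreceptor, ribbon and conventional synapse, bipolar cell, amacrine and horizontal cell, retinal ganglion cell, Mueller glia, retinal pigment epithelium, melanin synthesis, lens, corneal and conjunctival epithelium, stroma and extracellular matrix, iris, ciliary body and outflow tissue, skeletal muscle, endothelium, immune cell, erythrocyte, lacrimal and other gland, myelin, immediate early and stress, and housekeeping genes. For each list the median log2 fold of the tested members minus the median of all tested genes (-0.01) was set among 10000 random lists of the same size, matched in 20 bins of mean expression. The percentile describes these libraries and is not a p-value.

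Genes were named by a rule written before the data were examined. It took the 10 genes with the highest and the 10 with the lowest fold among those with a value of at least 10 in the higher library, the 5 most abundant genes of each library, the 3 members of each list with the highest mean, members called against most of their list, and Actb, Gapdh and Pax6. Genes without a symbol were skipped, 0 among the highest and 2 among the lowest. Members named because a count was 5 or fewer were chosen after their values were seen. Some genes that the rule took are not reported here.

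Settings chosen beforehand were also varied, with another added value (1 or 0.01), no minimum or a minimum of 5, a fold of 4, other scalings, and random lists matched in 10 bins or unmatched. The scalings were totals without the lens list, a trimmed mean of log ratios and a median of ratios. The trimmed mean and the median were computed on the RPKM values in place of the planned count methods. For the lens list, only the smallest reads that fit were taken out of the totals, and only 18 of its 26 genes had a value. This scaling may therefore take out too few. Equal summed values, calls from recovered reads and leaving out the rows with few decimals were added after the data were seen. Alternatives that need a column per technical replicate were not run.

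The steps were tested on simulated data that held counting error only, without technical or biological spread, and with 200 of 13978 genes changed. For the eye and retina comparison, reads and length were found, up to a shared factor, for 1500 of 1500 simulated genes. Of 200 genes changed by 1.5 or more on the log2 scale, 200 were called in the right direction, and 16 of 12241 unchanged genes were called. Of 100 random lists, 5 lay outside the central 95%, and all of 100 lists shifted by 1 were found. As nearly all simulated genes were unchanged, these numbers give no rate of wrong calls or missed lists for the real libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.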

Results

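RNA sequencing was used to measure gene expression in ocular tissue of wild-type Long Evans rats, a pigmented laboratory strain. The labels name 2 tissues, eye and retina, and 2 technical replicates for each tissue. RNA of 5 rats was pooled for each library. A single column of values was analysed per tissue. They are taken here as RPKM (reads scaled by gene model length and by the library's total reads), a unit inferred from the values. Each tissue is thus represented by 1 column of values from 1 pool, called its library here. Whether the column joins both technical replicates is not known, and none of the differences has a replicate check or a p-value. The tissue labels and titles set eye apart from retina, whereas the description of all 4 samples names retina mRNA, and the libraries are called here by their tissue label. Values were given for 14485 gene names. The values had been scaled by 28071917 reads in the eye library and 51944762 in the retina library. A gene of equal level thus had about 1.85 times as many reads in retina, while genes near 0 there rested on few reads.

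The comparison asked which genes were more abundant in the eye library than in the retina library. Genes of the lens, skeletal muscle, cornea and conjunctiva, connective tissue, myelin and pigment cells were far higher in the eye library. As lists, genes of rods, cones and retinal neurons lay lower there, with median folds from 1.59 for ganglion cell genes to 2.14 for rod genes, although most members of several of these lists were not called. With lens genes left out of the totals these medians were 1.38 and 1.87, and with equal summed values 2.47 and 3.34. Of 13259 genes with a value of at least 1 in either library, 2366 (17.8%) were at least 2-fold higher in the eye library and 1054 (7.9%) at least 2-fold lower. The differences toward the eye library were much the larger: 1203 genes were at least 4-fold higher and 97 at least 100-fold higher, against 12 genes at least 4-fold lower and 0 at least 100-fold lower.

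Whole reads could be recovered for most of these genes, and the exact 95% interval of the fold, which covers counting error only, lay above 1 for 2300 of 2307 higher genes and below 1 for 995 of 999 lower genes. The balance of the calls turned with 1 of the scalings, equal summed values, which was added after the data were seen. In those sums the lens genes held 35.9% in eye and 0.615% in retina. This scaling moved the log2 ratio by -0.64 before 0.1 was added, and less for genes of low value. With it, 26.4% of the called genes were higher in the eye library, against 69.2% with the values as deposited. The share was 70.2% with the trimmed mean, 70.7% with the median of ratios and 83.9% with totals without lens genes. Gene lists are therefore given relative to the median of all tested genes. A scaling moves all log2 ratios alike before 0.1 is added, so it could hardly change that difference.

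**Figure D1:**
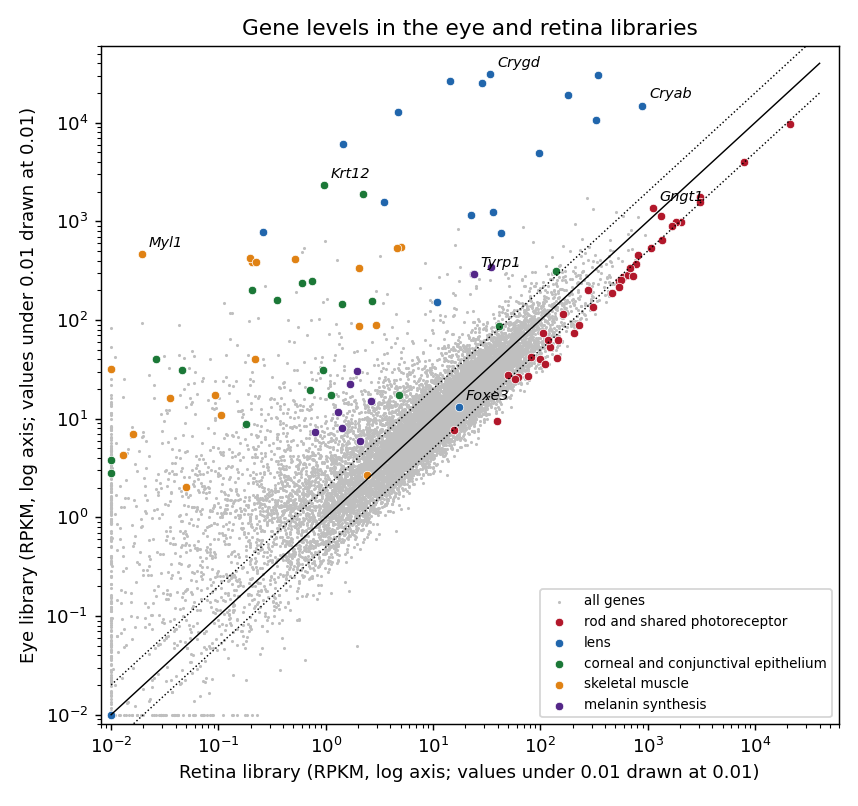
Each point is a gene, placed by its RPKM in the retina library (horizontal, log axis) and in the eye library (vertical, log axis). The solid line marks equal values and the dotted lines a 2-fold difference. Lens, corneal, muscle and melanin genes lie above the lines, except Foxe3, 1 muscle gene and Lenep, a lens gene listed at 0 in both, and most rod and shared photoreceptor genes lie near the lower dotted line.

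Photoreceptor genes were among the most abundant transcripts of the retina library. Gnat1, the alpha subunit of rod transducin, had a value of 7967 in retina and 3959 in eye, 2.01-fold lower in eye (interval 2.00 to 2.02). Of 15 tested rod genes, 11 were lower in the eye library and 0 higher. The list held 11.9% of the summed value in retina and 3.83% in eye. Its median was -1.08 relative to all genes, at percentile 0.0 of random lists of matched expression. Rom1, a disc rim protein, was 2.05-fold lower. The 4 members not called were Sag (3067 in retina and 1776 in eye), which encodes rod arrestin, Pde6b, Cnga1 and Gngt1, and Gngt1 had its higher value in the eye library (1371 against 1112).

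Genes shared by rods and cones behaved alike: 16 of 25 were lower in the eye library and 0 higher, with a relative median of -1.06 (percentile 0.0). Prph2, a disc rim protein, was at 3099 in retina and 1565 in eye, a 1.98-fold difference just short of the threshold. Rcvrn (recoverin) and Unc119, a lipid-binding chaperone of transducin, were 1.87-fold and 1.88-fold lower, also short of it. Rpgrip1, a protein of the connecting cilium, was 4.18-fold lower (interval 3.79 to 4.61). Of 15 cone genes, 7 were lower and 0 higher, with a relative median of -0.94 (percentile 0.0). Among them were Gnb3 (2.42-fold), a transducin subunit, Arr3 (2.22-fold), cone arrestin, and Pde6h (2.93-fold), the inhibitory subunit of the cone phosphodiesterase.

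Genes of the inner retina and of synapses lay lower in the eye library too. Of 15 synaptic genes, 7 were lower and 0 higher, with a relative median of -0.92 (percentile 0.01). Slc17a7, the vesicular glutamate transporter of photoreceptors and bipolar cells, was 2.69-fold lower and Syp (synaptophysin) 2.08-fold lower. Snap25, a vesicle fusion protein, was at 410 in retina and 373 in eye, and its small difference changed sign when lens genes were left out of the totals. Of 17 bipolar cell genes, 5 were lower (Grm6, Nyx, Lrit3, Lhx4 and Rgs11) and 0 higher, with a relative median of -0.88 (percentile 0.0). Pcp2 and Trpm1 had their higher values in retina, by 1.76-fold and 1.43-fold, and were not called. Of 14 amacrine and horizontal cell genes, 7 were lower and 0 higher, with a relative median of -0.95 (percentile 0.0). They included the glycine transporter gene Slc6a9 (2.11-fold), while Calb2 (calretinin) differed by 1.64-fold. Of 14 ganglion cell genes, 2 were lower (Isl2 and Opn4), with a relative median of -0.65 (percentile 0.35). Sncg, Thy1 and Nefl differed by 1.74-fold, 1.87-fold and 1.58-fold without reaching the threshold.

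These counts sat close to the 2-fold threshold and moved with the scaling. With lens genes left out of the totals, 4 rod genes, 10 shared photoreceptor genes, 4 cone genes, 3 synaptic genes, 3 bipolar genes, 4 amacrine and horizontal genes and 0 ganglion cell genes were lower, and 1 bipolar gene was higher (Tacr3, at 11.3 in eye and 6.08 in retina). With equal summed values the same lists had 14, 24, 11, 14, 16, 12 and 11 lower genes. At a fold of 4 they had 0, 1, 0, 0, 0, 0 and 0. Adding 1 to each value left 3 bipolar, 4 amacrine and horizontal and 1 ganglion cell gene lower.

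Genes of Mueller glia, the radial glia of the retina, did not stand apart. Their relative median was -0.12, at percentile 41.4 of the random lists, and 2 of 11 were higher in the eye library. Those were the intermediate filament genes Vim and Gfap, which other cell types also express. With equal summed values neither was called, and 2 other members (Slc1a3 and Kcnj10) were lower, so that the calls turned from 2 higher to 2 lower. Gfap was also not called with 1 added. Apoe was at 1114 in eye and 816 in retina, Clu at 453 and 322, and Dkk3 at 423 and 529, none of them called, and Apoe and Clu changed sign with equal summed values. Pax6, a transcription factor of eye development, was at 96.7 in eye and 111 in retina.

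Genes of the pigmented tissues were higher in the eye library. All 10 tested genes of melanin synthesis were higher, with a relative median of 3.20 (percentile 100). Dct, Tyrp1 and Pmel were at 342, 291 and 290 in eye, 9.81-fold, 12.4-fold and 12.2-fold above retina. Of 14 genes of the retinal pigment epithelium, the layer that recycles visual pigment, 11 were higher and 0 lower, with a relative median of 1.61 (percentile 100). With equal summed values, 6 of them were higher, and at a fold of 4, 3 were. Ttr (transthyretin) was 4.42-fold and Rgr, an opsin of that layer, 3.79-fold higher. Rrh, Trpm3 and Rdh10 were not called, and the value of Rrh (65.6 in eye and 43.5 in retina) changed sign with equal summed values.

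Lens genes dominated the eye library. Values were given for 18 of the 26 listed genes. These took 35.9% of the summed value of the eye library and 0.615% of that of retina, or at least 12.8% and 0.15% of the reads. The 5 most abundant genes of the eye library were all crystallins, the structural proteins of the lens: Crygd (30893), Cryba1 (30558), Crygb (26735), Crygc (25409) and Crygs (19099). Of 17 tested lens genes, 16 were higher in eye, with a relative median of 6.49 (percentile 100). Crygf, Cryge and Crygb were 4156-fold, 2706-fold and 1878-fold higher, Crygd was 908-fold higher and Cryba1 89.0-fold higher. Lgsn (lengsin), a lens protein, was at 776 in eye and 0.263 in retina. The gamma-crystallin genes are close paralogs, and how reads were split between them is not given in the sources used here, so their single values are uncertain. Foxe3, a transcription factor of the lens epithelium, was the lens gene not called, with 13.2 in eye and 17.4 in retina, and it was lower in eye with equal summed values.

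All 19 tested genes of the corneal and conjunctival epithelium were higher in eye, with a relative median of 5.82 (percentile 100) that was 4.96 with 1 added and 8.37 with recovered reads. Krt12, the keratin of the corneal epithelium, was 2428-fold higher (interval 1915 to 3127), at 2318 in eye and 0.955 in retina. Aldh3a1, an aldehyde dehydrogenase abundant in cornea, was 853-fold higher and Tkt (transketolase), also expressed in retina, 2.28-fold higher. All 22 genes of stroma and extracellular matrix were higher, with a relative median of 4.46 (percentile 100), or 3.16 with 1 added. Dcn (decorin) was 645-fold, the collagen gene Col1a2 108-fold and Sparc 4.30-fold higher. Of 10 genes of iris, ciliary body and outflow tissue, 8 were higher, with a relative median of 3.24 (percentile 100). Mgp (matrix Gla protein) was at 844 in eye and 16.9 in retina, Myoc (myocilin) was 12.1-fold and the water channel gene Aqp1 2.65-fold higher, while Cyp1b1 and Wfdc1 were not called.

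Skeletal muscle genes were higher in the eye library in 18 of 19 cases, with a relative median of 6.84 (percentile 100), or 5.03 with 1 added and 7.54 with recovered reads. Myl1, a myosin light chain, was at 466 in eye and 0.0192 in retina. The retina value stood for as few as 1 read, so that the interval of the fold ran from 4346 to 956642 and overlapped that of Crygf (2836 to 6362). With 1 added to each value, the log2 fold of Myl1 was 8.84, below that of Crygf at 11.27. Acta1 (skeletal alpha-actin) was 109-fold and Mylpf, a fast muscle myosin light chain, 116-fold higher. The troponin genes Tnni2 (429 in eye) and Tnnt3 (387), and Mb (myoglobin, 389), were at 0.198, 0.205 and 0.224 in retina. The gene of the muscle ryanodine receptor, found under an older symbol, was not called, at 2.68 and 2.40.

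Myelin genes were higher in the eye library in 12 of 13 cases, with a relative median of 3.95 (percentile 100), or 2.33 with 1 added. Mal was 117-fold and Pmp22, a protein of peripheral myelin, 3.03-fold higher, and Cnp was not called. Of 11 endothelial genes, 8 were higher, or 3 at a fold of 4, with a relative median of 1.76 (percentile 100). Plvap, a protein of fenestrated endothelium, was 12.6-fold higher, whereas Flt1, Cldn5 and Esam were not called. Cldn5, a tight junction gene of barrier endothelium, was at 34.6 in eye and 30.5 in retina, and Esam at 14.4 and 14.6. Cldn5 changed sign with equal summed values and Esam without lens genes in the totals. Of 13 immune cell genes, 11 were higher, with a relative median of 1.76 (percentile 100), among them Cd74 (13.4-fold), the invariant chain of MHC class II, Lyz2 (7.37-fold) and C1qc (3.41-fold). Csf1r and Cx3cr1 were not called.

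The erythrocyte and gland lists had only 2 tested genes each. Hbb-b1, a beta-globin gene, and Alas2, of heme synthesis, were 5.88-fold and 5.97-fold higher in eye, with a relative median of 2.53 (percentile 97.48). Slc4a1 was below the minimum, at 0.331 and 0.0672. In the gland list Pigr was at 1.12 in eye and listed at 0 in retina, Amy1a was 4.67-fold lower in eye (interval 3.21 to 7.01), and the relative median was 0.79 (percentile 29.4), or -0.10 with 1 added and 2.32 with 0.01 added. Ltf was below the minimum, at 0.0129 in eye.

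**Figure D2:**
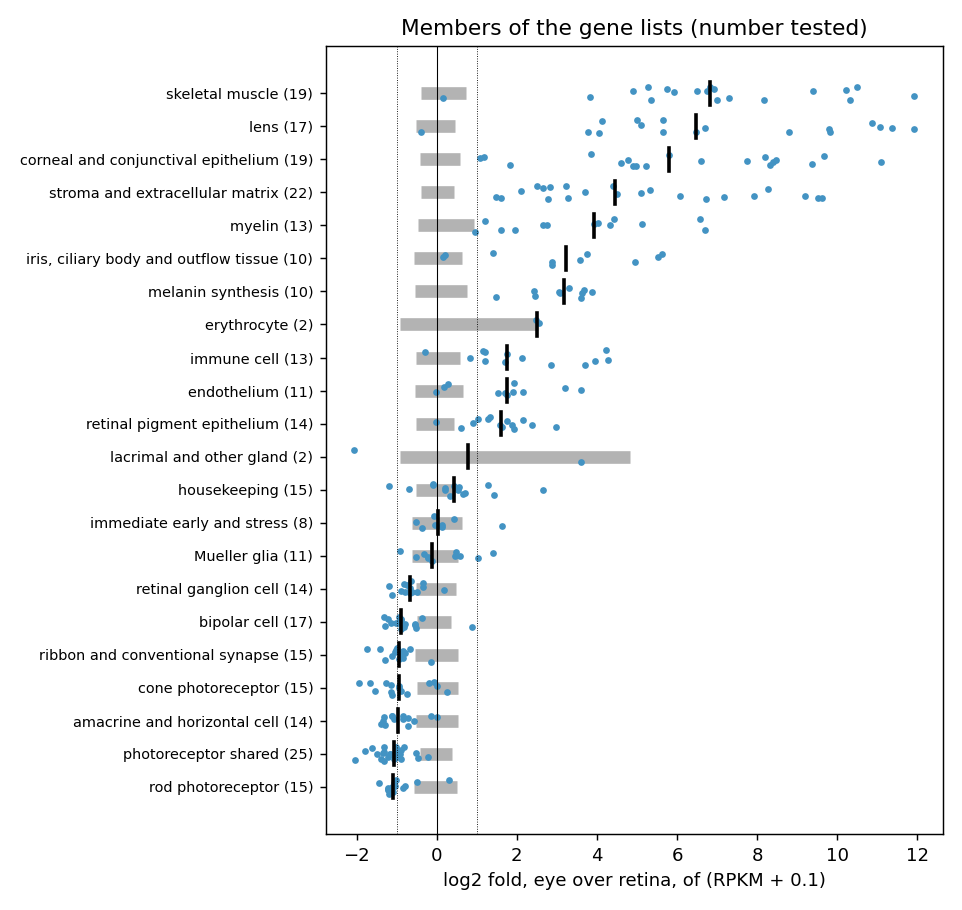
Each point is a tested gene of a list, placed by its log2 fold of eye over retina, and the number tested stands in brackets. Black bars are list medians, grey bars the central 95% of medians of 10000 random lists matched on expression, and dotted lines a 2-fold difference. The medians run from -1.10 for rod genes to 6.83 for skeletal muscle genes.

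Immediate early and stress genes did not stand apart, with a relative median of 0.05 (percentile 64.9), and 1 of 8 was higher in eye (Junb). With equal summed values Junb was not called, at a log2 fold of 0.99, and 1 gene (Dusp1) was lower. Dusp1 was at 25.2 in eye and 35.9 in retina, Ier2 at 29.1 and 29.9, and Egr1 at 19.2 and 17.7. Ier2 changed sign without lens genes in the totals and Egr1 with equal summed values. Of 15 housekeeping genes, 3 were higher (Actb, Rplp0 and B2m), 1 was lower (Gapdh) and 11 were not called, with a relative median of 0.44 (percentile 97.0). Actb (beta-actin) was at 1231 in eye and 509 in retina, and Rplp0, a ribosomal protein gene, at 657 and 242. Pgk1, of glycolysis, was at 402 and 279 and changed sign with equal summed values. Gapdh, also of glycolysis, had values of only 2.71 in eye and 6.28 in retina, 2.32-fold lower in eye (interval 1.85 to 2.92). Gapdh was not called without lens genes in the totals (log2 fold -0.99) or with 1 added (-0.97). With equal summed values Actb (0.63) and Rplp0 (0.80) were not called, and 1 housekeeping gene was higher and 2 were lower. Whether reads shared with pseudogenes affect the value of Gapdh is open.

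Among genes with a symbol and a value of at least 10 in the higher library, the 10 with the lowest fold lay between 3.69-fold and 4.57-fold lower in the eye library. They were led by Lamb3, a laminin chain, at 5.51 in eye and 25.1 in retina (interval 4.20 to 4.97). After it came Rpgrip1, Lig4, a DNA ligase (4.09-fold), Pitpnm3 (4.01-fold) and Crb2, a cell polarity protein of the retina (3.89-fold). Cacna2d4, a calcium channel subunit of photoreceptors, was at 19.3 and 71.0, 3.69-fold lower. Fam19a3, Fam65c and Jph4 had retina values between 13.9 and 44.4. Genes that overlap a neighbour, on either strand, may share its reads, since strand use in counting is not given in the sources used here.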

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

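The comparison with equal summed values, that with recovered reads and that without rows of few decimals were chosen after the data were seen, and the others before. The number of genes lower in the eye library, 1054 as reported, was 655 with 1 added to each value, 540 with totals without lens genes, 12 at a fold of 4 and 4264 with equal summed values. The number higher, 2366 as reported, was 1471 with a minimum of 5, 1203 at a fold of 4 and 1530 with equal summed values. These follow from how the alternatives are built: a larger added value shrinks low folds, a stricter filter tests fewer genes, and a scaling moves the log2 ratio, by 0.20 without lens genes and -0.64 with equal summed values, before 0.1 is added, so low values move less. The trimmed mean and the median of ratios moved it by 0.01 and 0.02 and gave 2385 and 2401 higher and 1014 and 997 lower genes. Recovered reads gave 2597 higher and 1126 lower, of which 2295 and 995 were shared with the reported calls. That setting changed several things together. Nothing was added where both values were above 0, at least 10 reads summed over both libraries were required, and the interval had to leave out 1.

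The scalings and the fold of 4 say little about the list medians relative to all genes. A scaling moves all log2 ratios alike before 0.1 is added, and the fold changes only the calls. No list median changed sign relative to all genes under the alternatives that gave a value, except that of the gland list. For its 2 tested genes, called in opposite directions, the relative median went from 0.79 to -0.10 with 1 added. That median was 2.32 with 0.01 added, and the immediate early median was 0.00 with no minimum. Lists with many retina values far below 1 moved with the added value: with 1 added the medians went from 6.84 to 5.03 for skeletal muscle, 5.82 to 4.96 for corneal epithelium, 4.46 to 3.16 for stroma and 3.95 to 2.33 for myelin. With recovered reads they were 7.54, 8.37, 5.01 and 4.12, and with 0.01 added they were 7.478, 7.485, 5.003 and 4.113. The erythrocyte median, of only 2 tested genes, was 2.19 with 1 added, 2.57 with 0.01 added, 2.49 with no minimum, 2.58 with a minimum of 5 and 2.56 with recovered reads, against 2.53. The gland list had no tested gene at a minimum of 5. With 10 bins the erythrocyte and housekeeping percentiles became 97.53 and 97.94, against 97.48 and 97.02, and with unmatched lists 96.15 and 93.7. The gland percentile went from 29.4 to 43.9 with 10 bins and 78.3 with unmatched lists. No paired analysis was possible because each tissue had a single column of values, and leaving out a technical replicate or a replicate test was not run for the same reason. Depth limits the genes near 0 in retina, where a fold rests on a few reads.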

Other observations

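The gene families and genes of these opening paragraphs were chosen after their values were seen. Most tested keratin, serpin, S100 and claudin genes were higher in the eye library, and some keratin and claudin genes also stand in the lists. Of 22 tested keratin genes, 20 were higher, with a median log2 fold of 5.44 (percentile 100 of random lists of matched expression), and of the 15 in no list 13 were higher (5.17). Also higher were 12 of 15 serpin genes (2.39) and 8 of 12 S100 genes (2.37), none of them in a list, and 8 of the 13 claudin genes in no list (2.19). With equal summed values 13 of these keratin, 10 serpin, 7 S100 and 8 claudin genes were higher, against 1, 0, 1 and 3 lower. Collagens in no list were mixed, 9 of 27 being higher and 6 lower, with a median of 0.57 that became -0.06 with equal summed values. Cytosolic ribosomal protein genes had a median of 1.07, and 42 of 70 were higher and 3 lower, but with equal summed values the median was 0.44 and only 6 were higher and 5 lower. Among single genes, Lypd2 was at 491 in eye and 0.60 in retina, Emp1 at 410 and 1.28, S100a6 at 447 and 3.21, and S100a4 at 571 and 16.2. Ptgds, prostaglandin D synthase, was at 1707 and 270, Txn1 (thioredoxin) at 882 and 69.1, and Tmsb4x (thymosin beta 4) at 625 and 86.1.

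Several neuronal families lay on the other side, and some of their members also stand in the lists. Of 13 ionotropic glutamate receptor genes, 5 were lower in the eye library and 0 higher (median -0.97, percentile 0.0), and of 7 metabotropic ones 4 were lower (-1.03, percentile 0.1). Of 67 potassium channel genes, 18 were lower and 9 higher (-0.63, percentile 0.0). Protocadherin genes had 5 lower and 0 higher of 43 (-0.44, percentile 0.0). GABA-A receptor subunit genes did not stand apart from random lists, with 1 lower of 12 (-0.50, percentile 3.0). Without lens genes in the totals these medians were still below 0, at -0.78, -0.84, -0.44, -0.26 and -0.31, with 4, 2, 12, 3 and 0 genes lower, and 9, 7, 47, 24 and 8 were lower with equal summed values. Potassium channel genes were nearly balanced in calls without lens genes in the totals, with 9 higher against 12 lower, and had 7 higher with equal summed values. Abundant single genes lower in eye were Eno2, the neuronal enolase (615 in retina and 299 in eye), Cpe, a peptide-processing enzyme (503 and 235), Sncb, beta-synuclein (469 and 230), Rtbdn, retbindin (423 and 195), Impdh1 (320 and 116) and Kcnj14, a potassium channel (293 and 127). Extreme percentiles were not particular to the families named so far. Zinc finger genes with Zfp symbols (-0.338, percentile 0.0) and Bardet-Biedl genes (-0.746, percentile 0.83) lay low. Mitochondrial ribosomal protein (0.355), complex I (0.498) and proteasome genes (0.409) lay high, at percentiles of 99.93 or above, but below 0 with equal summed values. The random lists were not matched on gene model length.

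Of the tests that follow, those on photoreceptor and lens genes were chosen after the results were seen. The bounds of those on Gapdh and ribosomal protein genes were written beforehand, though their low values are themselves a result of these data. The rules that decide on length and dilution were changed after their values were seen. Resampled intervals were added then, and with them the pseudogene test went from counting against its explanation to undecided. By its first rule, the rho of length and fold over the photoreceptor genes (-0.21), length was left open. A later rule on the deviation counted against it, until a condition on very short lengths, also set after they were seen, left it open again. No biological explanation was tested, since the tissues are the only groups.

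The 40 tested rod and shared photoreceptor genes had a median log2 fold of -1.09 but ran from -2.05 to 0.30. Counting error does not account for this, since the exact interval of 85.0% of them left out their median. Gene model length stays open: over 12795 genes short models had higher folds (rho -0.17), and taking that trend out in 20 bins left a median absolute deviation of 0.20, against 0.18 before, but the lengths are the smallest that fit, and for 6 of the 40 genes they were under 500 bp. Dilution of retinal RNA by RNA of other eye tissue may set the common level, but the deviation of 0.176 around the genes' own median is the same with or without a common factor and decides nothing. Without replicate libraries the technical part of the spread is unknown.

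Lens genes had values in the retina library, from 891 for Cryab to 0.263 for Lgsn. Carry-over of lens RNA of a single composition, as the only source, would give all of them nearly the same fold. Their log2 folds spanned 12.42 over 17 genes, and 8.22 without Foxe3. The span does not exclude carry-over beside expression of some of these genes in retina. For Crygb, Crygc, Crygd, Cryge and Crygf the log2 folds spanned 2.21, near the bound of 2 set after the results were seen. The counting intervals of that span reach to either side of the bound. Yet their folds were not the same within counting error. Intervals were 840 to 957 for Crygc and 856 to 963 for Crygd, against 1714 to 2061 for Crygb, 2313 to 3186 for Cryge and 2836 to 6362 for Crygf. As the split of reads between these paralogs is not known, carry-over as their only source is neither shown nor excluded. Reads shared between these paralogs and their own expression in retina stay open.

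Gapdh and 24 of 74 cytosolic ribosomal protein genes had values under 10 in both libraries. Reads shared with processed pseudogenes may be behind this, as the reference table names 81 pseudogenes of Gapdh and 10 of Actb, a single pair of genes. Yet the 24 low ribosomal protein genes had a median of 11.0 named pseudogenes against 11.5 for the others, and over all of them the number of named pseudogenes and the mean log2 value had a rho of -0.08 (resampled 95% interval -0.31 to 0.18), across genes that are not independent replicates. The point value met the bound written beforehand against this explanation (above -0.2), but the interval reaches past it, and the number of named pseudogenes says nothing of how alike they are. For the ribosomal protein genes, loss of short transcripts may also take part. Their length and level had a rho of 0.204 (interval -0.02 to 0.43), which decides neither way. These lengths are the smallest that fit, down to values such as 74 bp for Rpl39. That rho does not cover Gapdh, whose smallest length was 1276 bp, against 1264 bp for the abundant Actb. By these lengths, shortness does not set Gapdh apart from Actb.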
